A study of Homo sapiens with 6 samples.

How the data were processed

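RNA sequencing counts of 6 libraries from the human cell line MCF7, an estrogen receptor-positive breast cancer line, were analysed. Per the labels, 2 libraries each came from a clone labelled PSFFV (the control, also labelled parental), from a clone labelled as overexpressing BCL2 and from one labelled as overexpressing BCL-xL (BCLXL, encoded by BCL2L1). The cells were untreated, grown in RPMI with 10% serum, left to adhere overnight and harvested with trypsin the next day. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each of the 3 groups stands for 1 clone, so a difference between groups may belong to the clones and not to the gene overexpressed. The text says both clones for those labelled BCL2 and BCLXL.

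Per the labels' protocols, poly(A) RNA was made into stranded libraries and sequenced as single reads of 50 bases. The deposited counts are whole numbers of reads per Ensembl gene, and the submitters' processing notes name TopHat, Bowtie, HTSeq, DESeq2 and the hg19 build without versions. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes may not be separated. The authors' second table holds regularised log2 values scaled with DESeq2, per the file name and the processing notes, and served here only for an alternative test. The annotations at hand were of GRCh38 (GENCODE and RefSeq), another build than that of the files, so they gave names and gene types only and no coordinates are printed. Names were found for 43044 of the 53515 gene IDs (80.4%). The others, which may be retired IDs, took 1.22 to 3.07% of the counts per library.

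Gene counts summed to 26640305 and 12447234 in PSFFV replicates 1 and 2, 35587125 and 23811517 in BCL2 replicates 1 and 2, and 27097120 and 26188673 in BCLXL replicates 1 and 2. HTSeq's summary classes stayed out of library sizes and tests. Per 100 gene counts, reads in no gene numbered 11.3 to 17.2 and ambiguous reads 4.39 to 4.66. Reads without a unique position numbered 49.7 and 41.7 per 100 gene counts in the PSFFV libraries and 33.5 to 37.1 in the others. Such reads were not counted, so genes with near-identical copies (HLA genes, immunoglobulin constant genes, SAA1, TPI1 and its pseudogenes) have uncertain levels. XIST, TSIX and all genes of the Y chromosome (455 gene IDs) were held out of every test.

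CPM (counts scaled to the library total) were computed from the deposited counts with TMM factors. The floor of a count of 0 was taken as 3 counts, which is 0.114 and 0.257 CPM in PSFFV replicates 1 and 2, 0.0828 and 0.132 in BCL2 replicates 1 and 2, and 0.107 in each BCLXL library. It covers counting error only, since reads carry no molecular identifiers. No fold is given where a group had 3 counts or fewer, and only CPM are printed for such genes.

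Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM factors, edgeR's expression filter by group and 1 fit of all 6 libraries with group as the only factor. It had 3 residual degrees of freedom, and 18647 genes were tested. Calls are at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Biological variation was estimated at 0.225, and at 0.121 with replicate number as a block. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, adjusted over 33 lists. Each list's members were also adjusted over the list alone. An estimated correlation and fry served as alternatives. With the estimated correlation, 0 of 33 lists passed in each of the 3 comparisons. Even the fibroblast markers, with all 12 members called in BCLXL vs PSFFV, did not pass it (camera adjusted p = 0.162). A call lost under it therefore cannot tell a shifted list from an unshifted one here. The design, the alternatives, the lists and the rule for named genes were set before the data were examined, except where said otherwise. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

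The lists were the pro-survival and pro-apoptotic BCL2 family, death receptors with caspases and IAPs, glycolysis, pyruvate entry and TCA cycle, nuclear complex I, nuclear complexes III and IV, nuclear ATP synthase, mtDNA-encoded mRNAs, mitochondrial ribosome, mitochondrial calcium and dynamics, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, ATF4-linked amino acid supply, unfolded protein response, NRF2 and glutathione, hypoxia, p53 targets, estrogen response, luminal identity, basal and mesenchymal markers, S phase, G2/M, interferon response, antigen presentation, NF-kB and inflammation, autophagy and lysosome, cytosolic ribosomal proteins, replication-dependent histones, and markers of fibroblasts, blood cells and endothelium. A further 10 lists were written after some levels had been seen: intestinal epithelium, plasma cell immunoglobulins, smooth muscle, liver, exocrine pancreas, lung epithelium, squamous epithelium, brain, kidney and breast luminal transcription factors.

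The named genes are BCL2 and BCL2L1 in every comparison, and the 5 largest fitted changes per direction (an order without measured size where a group is at 0) among called genes with a group mean of at least 10 CPM and no overlap of the libraries. Added to these are the called member with the smallest adjusted p per direction of the lists of the BCL2 family, glycolysis, TCA cycle, fatty acid oxidation, estrogen response and luminal identity. For the 4 other lists with the smallest camera p, up to 2 called members are named. Of genes called in both clones, 5 per direction and up to 5 opposite ones are named. Genes named outside this rule are said to be so.

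On simulated counts of 18165 genes with known changes, the test without the block recovered 2.04% of 2-fold and 64% of 8-fold changes in BCL2 vs PSFFV, 0.813% and 66.0% in BCLXL vs PSFFV, and 6.10% and 71.6% in BCLXL vs BCL2, with 0 false calls in each. DESeq2 1.42.0 made 0, 0 and 1 false calls. With the replicate block, edgeR recovered 60.2% of 2-fold changes in BCL2 vs PSFFV and 60.2% in BCLXL vs PSFFV, and 67.1% in BCLXL vs BCL2, with 18, 17 and 29 false calls. Beside these stood 59, 74 and 143 recovered 2-fold and 96, 93 and 192 recovered 8-fold changes. The counts were drawn with the spread of the blocked fit and 1 replicate effect shared by all groups. The gain from the block is thus built in, while real deviations correlated at 0.29 to 0.58 between groups. Camera found the list shifted in the simulation in BCLXL vs PSFFV (adjusted p = 4.3e-64) and in BCLXL vs BCL2 (adjusted p = 9.8e-47), and 0 of the 32 other lists passed in either. These lists were random genes, each drawn independently. They cannot show how often camera passes an unshifted list whose genes vary together.

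The replicate numbers of the labels are shared by the 3 groups, and same-numbered libraries deviated together. Deviations from the group means correlated across genes at r = 0.58 between PSFFV and BCL2, 0.29 between PSFFV and BCLXL and 0.33 between BCL2 and BCLXL. The second principal component (10.3% of the variance) followed the numbers. The numbers were therefore taken to pair the libraries, and values from the fit with the replicate block (2 residual degrees of freedom) are given where they change the call of a named gene or list or move a printed count of genes by over 1.5 times.

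Alternatives were DESeq2's size factors, upper-quartile factors, no filter on low counts, a mean of at least 5 CPM, DESeq2's Wald test, limma on the deposited log2 values, a fit of only the 4 libraries compared, the replicate block, thinning to the smallest library, leaving out each library in turn and a test against a fold of 1.5 (glmTreat). Chosen after seeing the data were a fit of genes with a mean of at least 10 CPM in the 4 libraries labelled PSFFV or BCL2, and the replicate block on those 4 libraries alone.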

Results

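The transcriptomes of 3 groups of untreated MCF7 cells were compared, with 2 libraries per group. MCF7 is a luminal, estrogen receptor-positive breast cancer line. BCL2 and BCL-xL are anti-apoptotic proteins of the mitochondrial outer membrane, and per the labels each was overexpressed in 1 clone, set against a control clone labelled PSFFV, so every comparison is of 1 clone with another. Between 12447234 and 35587125 gene counts were available per library. Log CPM correlated across genes at r = 0.980 between the libraries labelled PSFFV, 0.984 between those labelled BCL2 and 0.984 between those labelled BCLXL. Same-numbered libraries labelled PSFFV and BCL2 correlated as closely as these replicates, at 0.987 for number 1 and 0.984 for number 2, against 0.973 and 0.979 across numbers. The libraries labelled BCLXL correlated with the other 4 at 0.896 to 0.908, and the first principal component (78.4% of the variance) set them apart from the other 4.

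BCL2 mRNA followed the labels and BCL2L1 mRNA did not. BCL2 (ENSG00000171791) stood at 29.4 ± 4.6 CPM (SD, n = 2) in the libraries labelled PSFFV, 396 ± 8.8 in those labelled BCL2 and 31.5 ± 0.16 in those labelled BCLXL. Its log2 fold change in BCL2 vs PSFFV was 3.76 (SE 0.17, edgeR adjusted p = 0.0012), while that in BCLXL vs PSFFV was 0.10 (SE 0.15, adjusted p = 0.705). BCL2L1 (ENSG00000171552), which encodes BCL-xL, was highest in the libraries labelled PSFFV, at 629 ± 13 CPM (SD, n = 2). It stood at 160 ± 41 CPM in those labelled BCLXL and 121 ± 14 CPM in those labelled BCL2. Its log2 fold change was −1.97 in BCLXL vs PSFFV (SE 0.21, adjusted p = 0.0018) and −2.38 in BCL2 vs PSFFV (SE 0.21, adjusted p = 0.020). BCL2L1 thus goes against the labels PSFFV and BCLXL, and every direction given here is between libraries as labelled. Over 16 alternative settings, the change of BCL2 in BCL2 vs PSFFV ranged from 3.16 to 3.92 and that of BCL2L1 in BCLXL vs PSFFV from −2.26 to −1.67, all past the threshold. The BCL2L1 call in BCL2 vs PSFFV was lost without PSFFV replicate 1, PSFFV replicate 2 or BCL2 replicate 1 (adjusted p from 0.058 to 0.098). Between the libraries labelled BCLXL and BCL2 the change of 0.41 (SE 0.20, adjusted p = 0.229) passed only with the replicate block (adjusted p = 0.036).

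**Figure D1:**
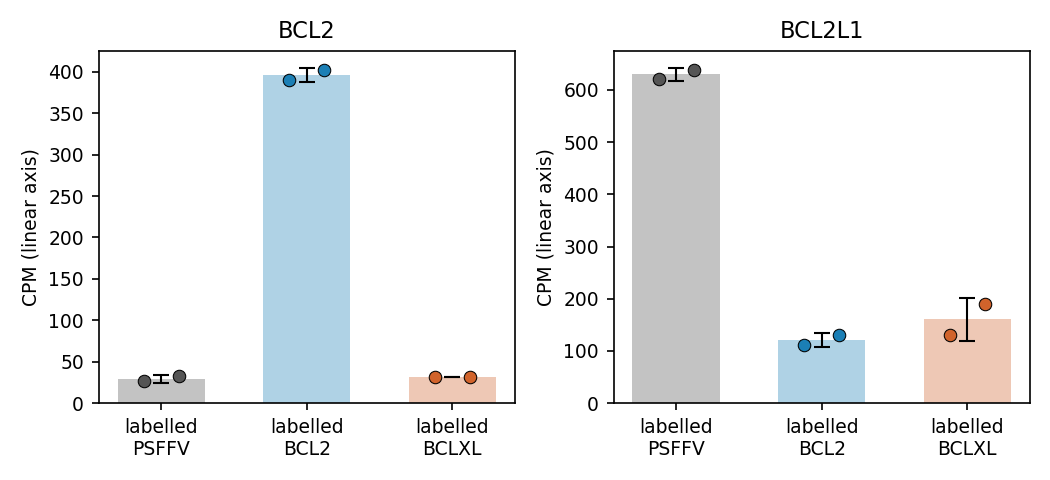
BCL2 (left) and BCL2L1 (right) in CPM on linear axes, with points for single libraries, bars for group means and error bars for SD (n = 2). BCL2 is highest in the libraries labelled BCL2 (396 CPM) and BCL2L1 in those labelled PSFFV (629 CPM).

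The libraries labelled BCLXL also held abundant transcripts of genes that were near 0 in the other 4. Of the fibroblast markers, COL3A1, a fibrillar collagen, stood at 116 ± 37 CPM (SD, n = 2) against 0.247 ± 0.14 in the libraries labelled PSFFV and 0.215 ± 0.070 in those labelled BCL2. The collagen gene COL1A2 stood at 106 ± 29 against 0.138 ± 0.074 and 0.234 ± 0.020 CPM. Of the blood cell markers, LYZ (lysozyme) stood at 28.6 ± 13 CPM and LAPTM5, a lysosomal membrane protein of blood cells, at 8.95 ± 0.87 CPM, while both lay under 1 CPM elsewhere. Summed over its list, the fibroblast markers came to 548 and 684 CPM in BCLXL replicates 1 and 2 and to 18.5 to 26.9 CPM in the other 4 libraries. The blood cell markers summed to 68.4 and 41.5 CPM against 0.684 to 1.5 CPM, and the endothelial markers to 27.5 and 36.1 CPM against 7.2 to 10.1 CPM. In all, 3991 tested genes lay under 1 CPM in each of the other 4 libraries and took 0.113 to 0.149% of their counts. The same genes took 1.23 and 1.09% of the counts in BCLXL replicates 1 and 2, where 232 and 199 of them reached 10 CPM.

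**Figure D2:**
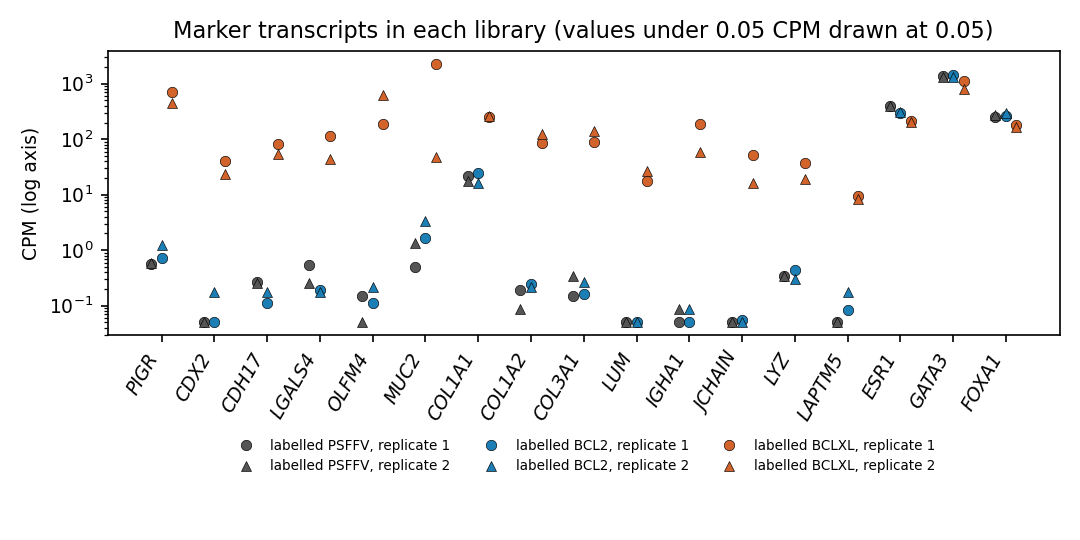
CPM (log axis) of marker genes in each of the 6 libraries, with circles for replicate 1 and triangles for replicate 2. The genes from PIGR to LAPTM5, several chosen after their values were seen, are higher in both libraries labelled BCLXL than in the other 4 (COL3A1 116 against 0.247 CPM in PSFFV), while ESR1, GATA3 and FOXA1 are abundant in all.

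The comparison of BCL2 with PSFFV asks which transcripts differ in the clone labelled as overexpressing BCL2. Besides BCL2, the genes furthest above the libraries labelled PSFFV were NR2F1, an orphan nuclear receptor, CTSZ, a lysosomal cysteine protease, SAA1, an acute-phase protein, and LIMCH1, an actin-binding protein. NR2F1 stood at 0.618 ± 0.34 CPM in the libraries labelled PSFFV and 20.6 ± 6.2 in those labelled BCL2 (SD, n = 2), a log2 fold change of 5.19 (SE 0.44, edgeR adjusted p = 0.016). CTSZ went from 0.618 ± 0.15 to 16.1 ± 1.9 CPM (4.63, SE 0.28, adjusted p = 0.0034). SAA1 (2.79, SE 0.32) and LIMCH1 (2.78, SE 0.32) each had an adjusted p of 0.045. Furthest below were LRFN5, a synaptic adhesion protein, AK7, an adenylate kinase of cilia, BRINP3, a secreted neural protein, SLIT2, an axon guidance ligand, and AC103770.1. LRFN5 fell from 69.6 ± 4.3 to 0.154 ± 0.094 CPM (−8.66, SE 0.36, adjusted p = 0.0012), on 8 and 2 counts in the libraries labelled BCL2. AK7 (−5.14, SE 0.46, adjusted p = 0.020), BRINP3 (−4.08, SE 0.25, adjusted p = 0.0034), SLIT2 (−4.03, SE 0.27, adjusted p = 0.0049) and AC103770.1 (−3.72, SE 0.22, adjusted p = 0.0034) fell too.

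The interferon response genes shifted upward as a list (camera adjusted p = 3.7e-16), with a median log2 fold change of 0.49 and 29 of 33 members above 0. With an estimated correlation the call was lost (adjusted p = 0.659), and the list did not pass fry (adjusted p = 0.140). In edgeR without the block, only BST2, a membrane protein that tethers budding viruses, passed over all genes. It stood at 33.3 ± 4.7 against 91.7 ± 0.98 CPM (1.46, SE 0.17, edgeR adjusted p = 0.048). DESeq2 called 8 members higher and 0 lower over all genes. Adjusted over the list alone, 12 members rose, and 8 rose over all genes with the replicate block. IFIT1, an RNA-binding antiviral protein, stood at 1.02 ± 0.23 against 3.31 ± 0.55 CPM (1.65, SE 0.29, adjusted p = 0.172, block 0.021).

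**Figure D3:**
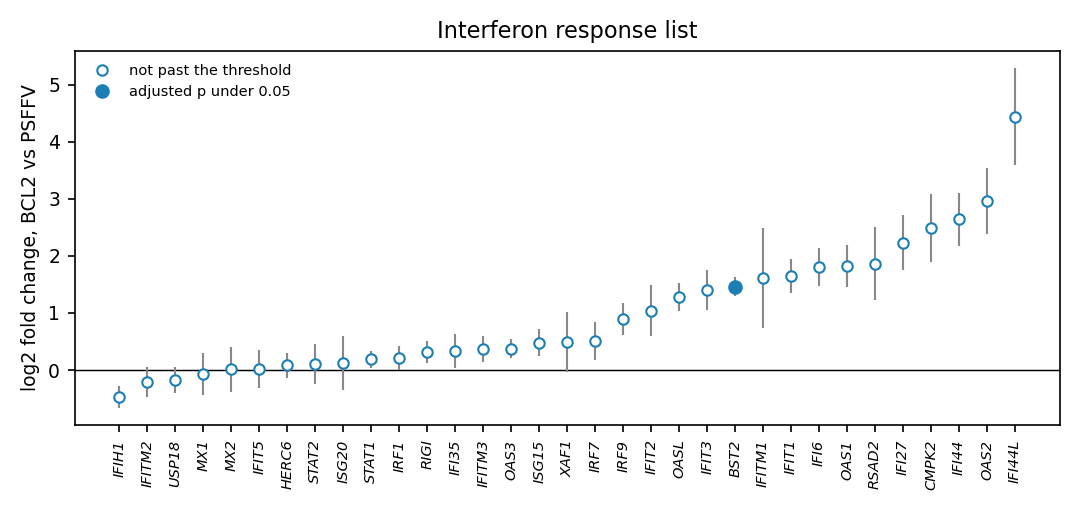
Log2 fold change in BCL2 vs PSFFV (vertical axis, bars are ±1 SE) of the 33 interferon response genes in order of size. Of these, 29 lie above 0 and 1 (BST2, filled) passed the threshold over all genes in edgeR without the replicate block, while DESeq2 called 8.

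The 13 mRNAs encoded by mtDNA shifted downward (median −0.36, camera adjusted p = 0.0015, lost with an estimated correlation at adjusted p = 0.804), with 0 called by edgeR over all genes or adjusted over the list alone, 0 by DESeq2, 3 lower at an unadjusted p under 0.05 and 1 lower with the replicate block. This list did not pass fry (adjusted p = 0.626). Its mRNAs took 6.17 and 5.74% of counts in the libraries labelled PSFFV and 5.33 and 4.93% in those labelled BCL2. In the pro-survival BCL2 family, BCL2 rose, BCL2L1 fell and 4 of 6 genes were not called, with the same calls adjusted over the list alone. EdgeR called 0 of the 15 pro-apoptotic family members, 23 glycolysis genes, 30 TCA cycle genes, 23 fatty acid oxidation genes, 23 estrogen response genes and 21 luminal genes, over all genes or adjusted over the list alone, and DESeq2 called 0 too. At an unadjusted p under 0.05 there were 0 pro-apoptotic genes, 2 fatty acid oxidation and 2 estrogen response genes were lower, and 1 glycolysis gene was higher and 1 lower, 2 TCA cycle genes higher and 1 lower, and 1 luminal gene higher and 2 lower. With the replicate block 1 glycolysis gene, 1 TCA cycle gene and 1 estrogen response gene rose, and in the luminal list 1 rose and 2 fell. The lists other than interferon response and mtDNA-encoded mRNAs had camera adjusted p from 0.074 to 0.986. With the replicate block 4 more lists passed, namely hypoxia (adjusted p = 0.0034) and the pro-apoptotic family (0.022) upward, cytosolic ribosomal proteins (0.0080) downward and replication-dependent histones (0.031) upward. All 4 calls were lost with an estimated correlation in the blocked fit (adjusted p = 0.764, 0.764, 0.859 and 0.868). Median, mean and camera direction differed in sign for the pro-survival, NRF2, estrogen response, basal and endothelial lists.

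In all, edgeR called 32 of 18647 genes between the libraries labelled BCL2 and PSFFV, 16 higher and 16 lower. With the replicate block it called 477 (291 higher and 186 lower), including all 32. Among the 9515 genes with a mean of at least 10 CPM in these 4 libraries, 19 were called (9 higher and 10 lower), 337 with the block (206 and 131) and 10 when these genes were fitted alone. Leaving out any 1 of the 6 libraries left 10 (without PSFFV replicate 1, BCL2 replicate 1 or either library labelled BCLXL) to 20 calls (without BCL2 replicate 2), and 11 without PSFFV replicate 2. The calls of SAA1, LIMCH1 and BST2 were lost without any 1 of the 6 libraries (adjusted p from 0.089 to 0.282), that of NR2F1 without PSFFV replicate 1, BCLXL replicate 1 or BCLXL replicate 2 (0.059 to 0.067) and that of AK7 without BCLXL replicate 1 or 2 (0.056 and 0.065). In the fit of only the 4 libraries compared, SAA1, LIMCH1, BST2, NR2F1 and AK7 were not called (9 calls in all), and SAA1, LIMCH1 and BST2 were not called after thinning or against a fold of 1.5. A mean of at least 5 CPM ended the calls of LIMCH1, AK7 and BST2, and limma that of BST2.

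The comparison of BCLXL with PSFFV asks the same of the clone labelled as overexpressing BCL-xL, with the limit that BCL2L1 was lower in the libraries labelled BCLXL. The 5 increases named by the rule of size are in genes without a single count in the libraries labelled PSFFV, where 3 counts would be 0.114 and 0.257 CPM. Their order rests on fitted changes from 0, which have no measured size, so other genes may have risen by more. Whether the 5 genes rose in the MCF7 cells was not tested. REG1A, a secreted lectin of the gut and pancreas, reached 80.1 ± 13 CPM (SD, n = 2) in the libraries labelled BCLXL and REG3A, an antibacterial gut lectin, 55.0 ± 51 CPM. DMBT1, a mucosal scavenger receptor, reached 47.4 ± 8.8 CPM, SLC40A1, the iron exporter ferroportin, 38.7 ± 0.84 CPM and CDHR1, a cadherin-related protein, 35.6 ± 4.1 CPM, with edgeR adjusted p from 0.00040 to 0.0056 over the 5 genes. The largest decreases among named genes were in PLCXD3, a phospholipase-like protein, from 27.7 ± 12 to 1.64 ± 0.30 CPM (−4.08, SE 0.38, adjusted p = 0.0012) and PCDH9, a protocadherin, from 13.4 ± 10 to 0.911 ± 0.43 CPM (−3.85, SE 0.83, adjusted p = 0.024). The other large decreases were in gene IDs without a name, of which ENSG00000239843 fell from 539 ± 155 to 42.9 ± 25 CPM (−3.65, SE 0.76, adjusted p = 0.022).

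All 12 fibroblast markers and all 9 tested blood cell markers rose, over all genes and adjusted over the list alone, with median log2 fold changes of 5.68 and 4.40 when members with a group at 0 are set to their bound. Of 8 endothelial markers 3 rose (4 rose and 1 fell adjusted over the list alone, 6 rose and 1 fell with the replicate block). The camera adjusted p of these lists were 3.6e-32, 6.6e-12 and 0.023, and with an estimated correlation they were 0.162, 0.285 and 0.285. Of 19 basal and mesenchymal genes 12 rose and 0 fell (15 adjusted over the list alone, camera adjusted p = 4.1e-15, and 0.162 with an estimated correlation). SERPINE1, an inhibitor of plasminogen activation, went from 0.456 ± 0.16 to 37.4 ± 3.2 CPM (6.25, SE 0.30, edgeR adjusted p = 0.00025) and SPARC, a matrix glycoprotein, from 0.0998 ± 0.020 to 59.1 ± 13 CPM (adjusted p = 0.00025).

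Interferon response genes rose in 22 of 33 cases (27 rose and 1 fell adjusted over the list alone, 29 and 1 with the block), at a median of 1.98 and a camera adjusted p of 5.2e-15 (adjusted p = 0.212 with an estimated correlation). IFI27, an interferon-inducible mitochondrial protein, went from 0.138 ± 0.074 to 30.6 ± 6.6 CPM (7.58, SE 0.42, edgeR adjusted p = 0.00033) and IFIT1 from 1.02 ± 0.23 to 18.4 ± 1.3 CPM (4.13, SE 0.30, adjusted p = 0.00059). Antigen presentation genes rose in 12 of 17 cases (14 adjusted over the list alone, camera adjusted p = 1.6e-09, and 0.285 with an estimated correlation). NF-kB and inflammatory genes rose in 9 of 20 (11 adjusted over the list alone, 12 rose and 1 fell with the block, camera adjusted p = 2.1e-05, and 0.348 with an estimated correlation). The fibroblast and blood cell markers, high in the same libraries, summed to 548 and 68.4 CPM in BCLXL replicate 1 and 684 and 41.5 CPM in BCLXL replicate 2. Intestinal genes summed to 4244 and 1552 CPM in BCLXL replicates 1 and 2. Whether the upward lists rose in the MCF7 cells was not tested.

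Nuclear respiratory chain, sterol and cell cycle lists shifted downward by smaller amounts. None of these lists held its call with an estimated correlation, under which 0 of all 33 lists passed. The mRNAs of mtDNA went the other way without passing camera (median 0.29, 12 of 13 above 0). EdgeR called 0 of them, and 4 rose with the replicate block. Of the breast luminal transcription factors, 7 of 9 were lower too in BCLXL vs PSFFV, with a median (−0.56) no smaller in size than those of the downward lists. ESR1, XBP1, TRPS1 and FOXA1 were called, TBX3 and TFAP2A were higher and not called, and the list was not tested as a set. Intestinal genes summed to 4244 and 1552 CPM in the same libraries. A fall specific to the downward lists is therefore not shown. Complex I genes fell in 4 of 36 cases (also 4 adjusted over the list alone, 17 fell and 2 rose with the replicate block, median −0.31, camera adjusted p = 0.00054, estimated correlation adjusted p = 0.212). Complexes III and IV fell in 5 of 19 (9 adjusted over the list alone, 14 with the block, median −0.40, camera adjusted p = 0.00067, estimated correlation adjusted p = 0.212). ATP synthase genes fell in 3 of 15 (8 adjusted over the list alone, 11 with the block, median −0.42, camera adjusted p = 0.00072, estimated correlation adjusted p = 0.388). Of 31 mitochondrial ribosome genes 1 fell (0 adjusted over the list alone, 12 with the block, camera adjusted p = 0.0075, estimated correlation adjusted p = 0.491). Cholesterol synthesis genes fell in 3 of 23 (3 adjusted over the list alone, 15 with the block, median −0.46, camera adjusted p = 0.00054, estimated correlation adjusted p = 0.285). Fatty acid synthesis genes fell in 4 of 14 (6 fell and 1 rose adjusted over the list alone, 7 fell and 2 rose with the block, camera adjusted p = 0.021, estimated correlation adjusted p = 0.285). G2/M genes fell in 4 of 26 (4 adjusted over the list alone, 17 with the block, median −0.40, camera adjusted p = 0.00011, estimated correlation adjusted p = 0.355). S phase genes fell in 0 of 24 (0 adjusted over the list alone, 4 at an unadjusted edgeR p under 0.05, 1 by DESeq2, 11 with the block, camera adjusted p = 0.0081, estimated correlation adjusted p = 0.714).

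In the BCL2 family, BCL2A1, a pro-survival member, went from 0.0190 ± 0.027 to 0.518 ± 0.18 CPM (edgeR adjusted p = 0.039), and BCL2L14, another member, from 0.319 ± 0.087 to 4.73 ± 3.2 CPM (3.81, SE 0.65, adjusted p = 0.010). BCL2L11, which encodes the pro-apoptotic protein BIM, fell from 113 ± 47 to 48.4 ± 10 CPM (−1.22, SE 0.32, adjusted p = 0.045). Of the 6 pro-survival genes 1 rose and 1 fell (the same adjusted over the list alone, 1 and 2 with the block), and of the 15 pro-apoptotic genes 2 rose and 1 fell (the same adjusted over the list alone, 3 and 2 with the block). LDHB, a lactate dehydrogenase subunit, went from 0.490 ± 0.16 to 113 ± 32 CPM (7.93, SE 0.35, adjusted p = 0.00025), 1 of 2 glycolysis genes of 23 that rose (2 adjusted over the list alone), and 9 fell with the block. PDP1, the phosphatase that activates pyruvate dehydrogenase, went from 17.0 ± 0.39 to 184 ± 72 CPM (3.44, SE 0.29, adjusted p = 0.00085), and SDHC, a succinate dehydrogenase subunit, from 102 ± 2.5 to 55.8 ± 11 CPM (−0.87, SE 0.17, adjusted p = 0.016). Of 30 TCA cycle genes 1 rose and 3 fell (1 and 1 adjusted over the list alone, 1 and 11 with the block, camera adjusted p = 0.048 downward, estimated correlation adjusted p = 0.348). ACSL5, an acyl-CoA synthetase, went from 0.204 ± 0.074 to 71.3 ± 5.4 CPM (8.54, SE 0.46, adjusted p = 0.00033) and CD36, a fatty acid transporter, from 128 ± 1.1 to 50.3 ± 4.7 CPM (−1.34, SE 0.20, adjusted p = 0.0064). Fatty acid oxidation genes rose in 2 and fell in 6 of 23 cases (2 and 7 adjusted over the list alone, 4 and 10 with the block, camera adjusted p = 0.286). LDHB, ACSL5, BCL2A1 and BCL2L14 lay under 1 CPM in the libraries labelled PSFFV, like many intestinal, fibroblast and blood cell transcripts. Those transcripts were abundant in the libraries labelled BCLXL. Whether these increases, or that of PDP1, arose in the MCF7 cells was not tested.

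Estrogen response genes shifted downward, and 7 of 9 breast luminal transcription factors were lower in BCLXL vs PSFFV (median −0.56). Called lower were ESR1, XBP1 (−0.95), TRPS1 (−1.12) and FOXA1 (−0.61). TFAP2C, GATA3 and SPDEF were lower and not called, and TBX3 and TFAP2A were higher (each 0.21) and not called. ESR1 and XBP1 belong to both lists, so a joint fall is partly built in. It cannot decide whether the estrogen response changed specifically. No specific change of estrogen response is shown. ESR1, the estrogen receptor, went from 397 ± 1.9 to 209 ± 2.7 CPM (−0.93, SE 0.12, edgeR adjusted p = 0.0043). AREG, an EGF receptor ligand of the same list, went from 0.0190 ± 0.027 to 1.86 ± 0.96 CPM (adjusted p = 0.012). The estrogen response list had 1 gene higher and 4 lower of 23 (2 and 6 adjusted over the list alone, 2 and 10 with the block) and shifted downward (camera adjusted p = 0.0078, estimated correlation adjusted p = 0.348). Of 21 luminal genes, 1 rose (MUC1, a mucin, from 19.8 ± 5.4 to 80 ± 37 CPM, 2.00, SE 0.40, adjusted p = 0.019) and 3 fell (the same adjusted over the list alone, 2 and 11 with the block, camera adjusted p = 0.056). The lists not yet given did not pass, with camera adjusted p from 0.064 to 0.979. They are the death receptors, mtDNA-encoded mRNAs, mitochondrial calcium, ATF4-linked, unfolded protein, NRF2, hypoxia, p53, autophagy, ribosomal protein and histone lists. Median, mean and camera direction differed in sign for the BCL2 family, glycolysis, mitochondrial calcium, fatty acid oxidation, ATF4-linked and NRF2 lists.

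In all, 3001 genes were called between the libraries labelled BCLXL and PSFFV, 2418 higher and 583 lower, and 6604 with the replicate block (3768 higher and 2836 lower). Of the higher genes 1499 (62.0%) lay under 1 CPM in all 4 libraries labelled PSFFV or BCL2. Among the 9515 genes with a mean of at least 10 CPM in those 4 libraries, 285 were higher and 524 lower (875 and 2501 with the block), and 118 were called when these genes were fitted alone. Without BCLXL replicates 1 and 2 in turn 1331 and 1422 genes were called, and without PSFFV replicates 1 and 2 in turn 1460 and 1725. Without BCLXL replicate 1 the calls of PCDH9, BCL2A1, BCL2L11, SDHC, CD36, MUC1 and ENSG00000239843 were lost, and without PSFFV replicate 1 those of BCL2A1, BCL2L11, SDHC, AREG and ENSG00000239843. Without PSFFV replicate 2 the calls of PCDH9, BCL2A1, SDHC and MUC1 were lost, and without BCLXL replicate 2 those of PCDH9, BCL2L11, AREG and ENSG00000239843. The adjusted p of these lost calls lay between 0.056 and 0.230. A mean of at least 5 CPM ended the calls of PCDH9, BCL2L11, SDHC and ENSG00000239843, no filter those of BCL2A1 and BCL2L11, and a fold of 1.5 those of BCL2A1, BCL2L11 and SDHC. DESeq2 did not call BCL2A1, and upper-quartile factors and limma did not call BCL2L11.

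The comparison of BCLXL with BCL2 asks where the clones differ from each other. IGHM and IGHG3, immunoglobulin heavy chain genes, HMGCS2, an enzyme of ketone body synthesis, TNC, the matrix protein tenascin-C, and SOD3, an extracellular superoxide dismutase, had 0 counts in both libraries labelled BCL2, where 3 counts would be 0.0828 and 0.132 CPM. In the libraries labelled BCLXL they stood at 43.9 ± 43, 30.3 ± 17, 28.4 ± 18, 22.7 ± 8.1 and 21.7 ± 10 CPM (SD, n = 2), with edgeR adjusted p from 0.00059 to 0.0055. The level of IGHG3 is uncertain, since reads that match several constant genes were not counted. Intestinal, plasma cell, fibroblast and blood cell transcripts were abundant in the libraries labelled BCLXL. Whether these 5 genes rose in the MCF7 cells was not tested. Lower than in the libraries labelled BCL2 were S100A8 and S100A9, the subunits of calprotectin, SAA1, BCL2 and PLCXD3. S100A8 stood at 73.7 ± 34 against 5.47 ± 3.3 CPM (−3.75, SE 0.56, adjusted p = 0.0055) and S100A9 at 161 ± 59 against 18.5 ± 7.5 CPM (−3.12, SE 0.40, adjusted p = 0.0030). SAA1 stood at 11.9 ± 1.9 against 1.14 ± 0.30 CPM (−3.37, SE 0.32, adjusted p = 0.0010), BCL2 changed by −3.65 (SE 0.17, adjusted p = 0.00019) and PLCXD3 by −3.06 (SE 0.37, adjusted p = 0.0026). S100A8 and S100A9 also differed between the libraries labelled BCL2 and PSFFV with the replicate block (adjusted p = 0.00022 and 8.6e-05) and not without it (0.385 and 0.264).

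Antigen presentation genes rose in 11 of 17 cases (14 rose and 1 fell adjusted over the list alone, 15 and 1 with the block, camera adjusted p = 7.6e-07, estimated correlation adjusted p = 0.343). CD74, the class II invariant chain, stood at 2.42 ± 0.066 CPM in the libraries labelled BCL2 and 119 ± 51 in those labelled BCLXL (5.61, SE 0.38, edgeR adjusted p = 0.00039). HLA-B, a class I chain, stood at 38.0 ± 5.2 and 208 ± 51 CPM (2.45, SE 0.21, adjusted p = 0.00085). Its level is uncertain, since reads that match several HLA genes were not counted. Interferon response genes rose in 15 and fell in 1 of 33 cases (18 and 1 adjusted over the list alone, 23 and 1 with the block, camera adjusted p = 1.3e-05, estimated correlation adjusted p = 0.279). The fall was in BST2 (−1.96, SE 0.17, adjusted p = 0.00089). NF-kB and inflammatory genes rose in 9 and fell in 2 of 20 cases (11 and 3 adjusted over the list alone, 11 and 4 with the block, camera adjusted p = 0.00096, estimated correlation adjusted p = 0.426). Basal and mesenchymal genes rose in 13 of 19 (14 adjusted over the list alone, camera adjusted p = 1.6e-13, estimated correlation adjusted p = 0.120). All 12 fibroblast and 9 blood cell markers and 4 of 8 endothelial markers rose (12, 9 and 6 adjusted over the list alone, 7 endothelial markers with the block). Their camera adjusted p were 2.5e-32, 6.3e-11 and 0.0065, and 0.086, 0.279 and 0.279 with an estimated correlation. Median changes with bounds for members at 0 were 6.85, 4.30 and 2.25. Intestinal and plasma cell transcripts were abundant in the libraries labelled BCLXL as well. Whether the upward lists of this comparison, with CD74 and HLA-B, rose in the MCF7 cells was not tested.

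Of the lists that shifted downward, none held its call with an estimated correlation, under which 0 of all 33 lists passed. The breast luminal transcription factors were lower as well in sum (4234 and 4160 CPM in BCL2 replicates 1 and 2, 2740 and 2207 CPM in BCLXL replicates 1 and 2). GATA3 and XBP1 were the largest parts, at 1432 and 1525 CPM in BCL2 replicate 1. TFAP2A, TBX3 and TFAP2C overlapped between the groups, PGR was near 0, and the list was not tested in this comparison. Intestinal, fibroblast and blood cell transcripts were abundant in the libraries labelled BCLXL. A fall specific to the downward lists is not shown here either. Complex I genes fell in 4 of 36 (0 adjusted over the list alone, 17 with the block, camera adjusted p = 0.0014, estimated correlation adjusted p = 0.279). Complexes III and IV fell in 2 of 19 (7 adjusted over the list alone, 10 with the block, camera adjusted p = 0.0056, estimated correlation adjusted p = 0.279) and ATP synthase in 3 of 15 (4 adjusted over the list alone, 11 with the block, camera adjusted p = 0.0090, estimated correlation adjusted p = 0.501). Cholesterol synthesis genes fell in 5 of 23 (5 adjusted over the list alone, 15 with the block, camera adjusted p = 0.00019, estimated correlation adjusted p = 0.279). Fatty acid synthesis genes fell in 6 of 14 (7 fell and 1 rose adjusted over the list alone, 9 and 1 with the block, camera adjusted p = 0.017, estimated correlation adjusted p = 0.279). Autophagy and lysosome genes fell in 5 of 21 (8 adjusted over the list alone, 9 fell and 2 rose with the block, camera adjusted p = 0.026, estimated correlation adjusted p = 0.279). Histones fell in 1 of 14 (1 adjusted over the list alone, 8 with the block, camera adjusted p = 0.0065, estimated correlation adjusted p = 0.572). G2/M genes fell in 1 of 26 (0 adjusted over the list alone, 21 with the block, camera adjusted p = 0.00038, estimated correlation adjusted p = 0.381). S phase genes fell in 0 of 24 (0 adjusted over the list alone or by DESeq2, 1 higher and 2 lower at an unadjusted edgeR p under 0.05, 10 fell and 1 rose with the block, camera adjusted p = 0.026, estimated correlation adjusted p = 0.676) and mitochondrial ribosome genes in 0 of 31 (0 adjusted over the list alone or by DESeq2, 2 at an unadjusted edgeR p under 0.05, 8 with the block, camera adjusted p = 0.033, estimated correlation adjusted p = 0.587). Of 23 estrogen response genes 1 rose and 5 fell (1 and 7 adjusted over the list alone, 3 and 13 with the block, camera adjusted p = 0.0073, estimated correlation adjusted p = 0.343), among them SLC39A6, a zinc transporter, at 1453 ± 119 against 519 ± 91 CPM (−1.48, SE 0.18, edgeR adjusted p = 0.0025).

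The mRNAs of mtDNA were higher in 4 of 13 cases (7 adjusted over the list alone, 10 with the block) and passed camera only with the block (adjusted p = 0.042, against 0.062), a call lost with an estimated correlation in the blocked fit (adjusted p = 0.656). They took 9.10 and 7.03% of the counts in BCLXL replicates 1 and 2. TPI1, a glycolytic isomerase, stood at 803 ± 55 CPM in the libraries labelled BCL2 and 549 ± 0.74 in those labelled BCLXL (−0.55, SE 0.14, edgeR adjusted p = 0.038), and 2 glycolysis genes rose and 1 fell (2 and 4 adjusted over the list alone, 3 and 14 with the block). The luminal transcription factors ELF3 (1.02, SE 0.22, adjusted p = 0.021) and FOXA1 (−0.66, SE 0.14, adjusted p = 0.021) moved apart, and of 21 luminal genes 1 rose and 2 fell (the same adjusted over the list alone, 4 and 9 with the block). LDHB, PDP1, ACSL5 and AREG were again higher and SDHC, CD36 and BCL2L11 again lower, with adjusted p from 0.00019 to 0.026. Whether the higher genes rose in the MCF7 cells was again not tested. In the BCL2 family, BCL2A1 (adjusted p = 0.014) and BCL2L14 (2.85, SE 0.57, adjusted p = 0.017) were higher, and 1 pro-apoptotic gene rose and 2 fell (3 and 3 adjusted over the list alone, 4 and 4 with the block). The lists not named as passing had camera adjusted p from 0.062 to 0.777. Median, mean and camera direction differed in sign for the BCL2 family, glycolysis, mitochondrial calcium, fatty acid oxidation, ATF4-linked, NRF2 and luminal lists.

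Between the libraries labelled BCLXL and BCL2, 3208 genes were called, 2535 higher and 673 lower, and 6775 with the replicate block (3924 and 2851). Of the higher genes 1563 (61.7%) lay under 1 CPM in all 4 libraries labelled PSFFV or BCL2, and among the 9515 genes of at least 10 CPM there 328 were higher and 574 lower (969 and 2468 with the block). The calls numbered 297 when these genes were fitted alone. Without BCLXL replicates 1 and 2 in turn 1495 and 1655 genes were called, and without BCL2 replicates 1 and 2 in turn 1989 and 1916. The call of TPI1 was lost without any 1 of the 6 libraries (adjusted p from 0.050 to 0.223). Without BCLXL replicate 1 those of BCL2A1, BCL2L14, BCL2L11, SDHC, ELF3 and FOXA1 were lost too, and without BCLXL replicate 2 those of BCL2L11, ELF3 and FOXA1. Without BCL2 replicate 1 those of BCL2A1, SDHC, ELF3 and FOXA1 were lost, and without BCL2 replicate 2 those of BCL2L14, SDHC and FOXA1 (adjusted p of these from 0.051 to 0.225). A mean of at least 5 CPM ended the calls of TPI1, SDHC and BCL2L11, and a fold of 1.5 those of TPI1, SDHC, ELF3 and FOXA1. TPI1 was also not called with only the 4 libraries compared, nor SDHC after thinning.

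The genes that differed from PSFFV in both the BCL2 and the BCLXL clone were then counted. CTSZ and NR2F1 were higher in both, at 39.5 ± 6.5 and 11.4 ± 1.0 CPM in the libraries labelled BCLXL (5.92, SE 0.29, edgeR adjusted p = 0.00025 and 4.35, SE 0.43, adjusted p = 0.0015). S100A6, a calcium-binding protein, stood at 0.428 ± 0.12, 2.76 ± 0.040 and 161 ± 37 CPM in the libraries labelled PSFFV, BCL2 and BCLXL. LIMCH1 (2.44 in BCLXL vs PSFFV, SE 0.31, adjusted p = 0.0038) and LAMA3, a laminin chain (1.89 and 2.40), were also higher in both. The libraries labelled BCLXL also held abundant intestinal, fibroblast and blood cell transcripts. Whether the increases there arose in the MCF7 cells was not tested. BCL2L1, LRFN5 (−2.79 in BCLXL vs PSFFV), BRINP3 (−2.59), SLIT2 (−1.22) and AC104793.1 (−1.94 and −2.45) were lower in both. PDE4B, a cAMP phosphodiesterase, and SERPINA3, a secreted protease inhibitor, went opposite ways. PDE4B stood at 2.44 ± 0.55 CPM in the libraries labelled PSFFV and 8.77 ± 1.5 in those labelled BCLXL (1.86, SE 0.34, adjusted p = 0.020), with 0 counts in those labelled BCL2 (adjusted p = 0.034), where 3 counts would be 0.0828 and 0.132 CPM. SERPINA3 stood at 65.9 ± 4.1, 189 ± 5.8 and 25.5 ± 1.8 CPM in the libraries labelled PSFFV, BCL2 and BCLXL (1.52, SE 0.14, adjusted p = 0.020 and −1.37, SE 0.14, adjusted p = 0.0016).

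Called the same way in both comparisons were 17 genes, 7 higher and 10 lower, where independent lists of these sizes would share 2.07 and 0.50, and 2 genes went opposite ways, where 2.57 would. Simulated unchanged groups against the same controls gave 0 in each of 20 draws. The test without the block made 0 false calls on simulated counts, so this outcome was close to fixed in advance. It cannot show what shared controls add where many genes are changed. With the replicate block 189 genes went the same way (90 higher and 99 lower, against 58.8 and 28.3 for independent lists) and 77 opposite ways (against 81.8), while the simulated groups gave 0.85 on average and at most 2. The 2 control libraries do not allow a split, so part of the excess may come from the shared controls. Both libraries are of 1 clone, and a trait of that clone alone would appear as a change in both comparisons. This holds for BCL2L1 too. Log2 fold changes correlated across genes at r = 0.27, against 0.56 in the simulated groups, and their covariance was 0.34 against 0.060. The simulated groups held no changed genes and shared the same mean levels, so these values are not like for like. The correlation lay between 0.13 (without BCL2 replicate 1) and 0.55 (without PSFFV replicate 1) when a library was left out. Without any 1 of the 6 libraries the BCL2 vs PSFFV calls of S100A6, LAMA3, AC104793.1 and SERPINA3 were lost (adjusted p from 0.078 to 0.439). That of PDE4B was lost without any library other than BCL2 replicate 2 (0.059 to 0.107), and leaving out a library left 5 to 7 genes called the same way, or 14 without BCL2 replicate 2. The fit of only the 4 libraries compared and the test against a fold of 1.5 also ended the calls of S100A6, LAMA3, AC104793.1 and SERPINA3 in BCL2 vs PSFFV. That of PDE4B ended with only the 4 libraries and after thinning (adjusted p up to 0.178), and those of S100A6, LAMA3 and AC104793.1 after thinning and with a mean of at least 5 CPM. Limma did not call S100A6 and upper-quartile factors did not call AC104793.1. In BCLXL vs PSFFV, leaving out PSFFV replicate 2 (SLIT2), PSFFV replicate 1 (PDE4B), BCLXL replicate 1 or BCLXL replicate 2 (both genes) ended their calls (0.062 to 0.135), and a fold of 1.5 ended that of SLIT2.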

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

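The 2 genes of this part were picked after the results were seen, because each passed the threshold in opposite directions in the 2 clones set against the same libraries labelled PSFFV. A difference between the clones follows from that choice, so the BCLXL vs BCL2 p-values below restate it and are no independent evidence. For PDE4B the edgeR adjusted p in BCLXL vs BCL2 was 0.00063, with 0 counts in both libraries labelled BCL2 and 8.77 ± 1.5 CPM (SD, n = 2) in those labelled BCLXL. For SERPINA3 it was 0.00021, with a log2 fold change of −2.89 (SE 0.14), from 189 ± 5.8 CPM in the libraries labelled BCL2 to 25.5 ± 1.8 CPM in those labelled BCLXL.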

How the results depend on the processing

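Of the settings in this part, the replicate block on 4 libraries and the restriction to genes of at least 10 CPM were chosen after the data were seen, and the others before. DESeq2's size factors, upper-quartile factors and no filter kept all 3 counts of called genes within 1.5 times. The genes called in BCL2 vs PSFFV (32) became 10 with a mean of at least 5 CPM, 220 with DESeq2's Wald test, 9 with only the 4 libraries compared, 13 after thinning, 17 against a fold of 1.5, 477 with the replicate block, 2115 with the replicate block on the 4 libraries, 10 when genes of at least 10 CPM were fitted alone (19 of these were called in the full fit and 337 with the block) and 10 to 20 without single libraries. Those in BCLXL vs PSFFV (3001) became 899 with at least 5 CPM, 6604 with the replicate block, 1922 against a fold of 1.5, 118 when genes of at least 10 CPM were fitted alone (809 in the full fit) and 1331 to 2851 without single libraries. Those in BCLXL vs BCL2 (3208) became 1068 with at least 5 CPM, 6775 with the replicate block, 297 when genes of at least 10 CPM were fitted alone (902 in the full fit) and 1495 to 3254 without single libraries. Fitting only genes of at least 10 CPM also lowered the prior degrees of freedom from 3.77 to 2.71, and whether this made the calls fewer was not tested. The cause of the other shifts was not tested either, except that filters and left-out libraries leave fewer genes or libraries.

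Genes called the same way in both clones (17) and in opposite ways (2) became 7 and 1 with at least 5 CPM, 86 and 29 with DESeq2, 7 and 0 with only the 4 libraries compared, 189 and 77 with the replicate block, 8 and 1 after thinning, and 8 and 1 against a fold of 1.5. Without single libraries they numbered 5 to 14 and 0 to 1. The correlation of the fold changes (0.27) became 0.37 with no filter, 0.22 with at least 5 CPM, 0.20 with DESeq2, 0.070 with limma on the deposited log2 values, 0.22 after thinning, and 0.13 to 0.55 without single libraries. The lists passing camera in BCL2 vs PSFFV (2) became 5 with limma, 4 with only the 4 libraries compared, 6 with the replicate block, 0 with an estimated correlation, 1 with fry and 3 to 8 without single libraries. In BCLXL vs PSFFV and BCLXL vs BCL2, 0 lists passed with an estimated correlation (smallest adjusted p = 0.162 and 0.086), and 14 to 21 and 18 to 20 passed without single libraries. The 1 list passing fry in BCL2 vs PSFFV was nuclear complexes III and IV (fry adjusted p = 0.0023), which camera did not call (adjusted p = 0.375). Interferon response (fry adjusted p = 0.140) and the mtDNA-encoded mRNAs (fry adjusted p = 0.626) did not pass fry. The cause of these shifts was not tested.

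BCL2 in BCL2 vs PSFFV and BCL2L1 in BCLXL vs PSFFV kept direction and call in all 16 settings. Without PSFFV replicate 1, BCL2 in BCLXL vs PSFFV, which was not called, changed sign to −0.044, and its values lay between −0.044 and 0.27 over the left-out libraries. Of the 89 other results for named genes, that one included, 57 kept direction and call, 30 lost the call in at least 1 setting and 1 (BCL2L1 in BCLXL vs BCL2) gained it with the replicate block, which ended no call of a named gene. Calls were lost most often without BCLXL replicate 1 (28 results) or 2 (22), PSFFV replicate 1 (19) or 2 (16) or BCL2 replicate 1 (14) or 2 (11), against a fold of 1.5 (16), with at least 5 CPM (15), with only the 4 libraries compared (11) and after thinning (8). In the fits that left a group with 1 library, that library was assumed to vary like the others. PSFFV replicate 2 was the shallowest library, and the simulated recovery of 2.04% of 2-fold changes in BCL2 vs PSFFV leaves most changes of that size uncalled.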

Other observations

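The tests in this part were chosen after the results were seen, except the equal-depth test of the replicate numbers. In a fit pooled over the 3 groups, libraries numbered 2 differed from those numbered 1, and no group was tested on its own. In the blocked edgeR fit 3303 genes differed by number, 1743 higher and 1560 lower in replicate 2. Of the lists, 9 passed camera between the numbers and 0 passed with an estimated correlation. S phase genes were higher in 19 of 24 cases (camera adjusted p = 2.3e-15, and 0.951 with an estimated correlation), among them RRM2, a ribonucleotide reductase subunit (log2 fold change 0.85), and CCNE2, cyclin E2 (1.06). Hypoxia response genes were lower in 11 of 15 (adjusted p = 1.5e-12, estimated correlation adjusted p = 0.508), among them the transcription factor BHLHE40 (−1.27). ATF4-linked amino acid genes were lower in 13 and higher in 1 of 24 (adjusted p = 2.3e-09, estimated correlation adjusted p = 0.951), among them ALDH1L2, a mitochondrial folate enzyme (−2.22). Glycolysis genes were lower in 8 and higher in 1 of 23 (adjusted p = 3.6e-06, estimated correlation adjusted p = 0.838), among them PFKFB4 (−1.67) and ALDOC (−1.61). These genes were chosen after their values were seen. The mitochondrial ribosome (adjusted p = 0.0038), histone (0.0058) and mitochondrial calcium (0.032) lists also shifted upward, and the pro-apoptotic (0.0066) and estrogen response (0.014) lists downward, with estimated correlation adjusted p of 0.951, 0.951, 0.951, 0.838 and 0.951. The lists of G2/M (adjusted p = 0.114), ATP synthase (0.116), fatty acid synthesis (0.669), cholesterol synthesis (0.759), fatty acid oxidation (0.845) and the TCA cycle (0.868) did not pass.

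At equal depth, 72.7% of the genes that differed by replicate number were called again in the same direction, which argues against depth as the cause. Reads in no gene also moved with the number, at 14.4 and 11.3 per 100 gene counts in PSFFV replicates 1 and 2, 17.2 and 11.4 in BCL2 replicates 1 and 2, and 16.3 and 15.5 in BCLXL replicates 1 and 2. Library quality and preparation therefore stay open beside growth conditions, and neither these nor a biological explanation was tested.

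Intestinal genes were among the abundant transcripts of the libraries labelled BCLXL that lay near 0 in the other 4. MUC2, the mucin of goblet cells, stood at 2299 and 48.0 CPM in BCLXL replicates 1 and 2, PIGR, the receptor that carries IgA across epithelium, at 701 and 452 CPM, OLFM4, a crypt marker, at 187 and 626 CPM, and CDX2, an intestinal transcription factor, at 40.6 and 23.8 CPM. Summed over the list, intestinal genes came to 4244 and 1552 CPM, against 25.2 to 35.5 CPM in the other 4 libraries. The plasma cell immunoglobulins summed to 648 and 214 CPM against 1.85 to 2.62 CPM, and the replicates also differed in REG4 (162 and 3.79 CPM) while COL3A1 went the other way (89.7 and 141 CPM).

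The first pattern is BCL2L1, highest in the libraries labelled PSFFV. Dilution by other RNA in the libraries labelled BCLXL cannot account for the libraries labelled BCL2, which lack that RNA. These had a log2 fold change of −2.38 (SE 0.21) against PSFFV. In BCLXL vs PSFFV, the change of BCL2L1 lay between −2.26 and −1.67 over 16 settings. That of BCL2 lay between −0.044 and 0.27, and the breast luminal transcription factors between −1.12 and 0.21. Equal dilution of all MCF7 transcripts would lower these as much, so the values argue against dilution as the only cause. An exchange of the labels PSFFV and BCLXL may account for this first pattern. BCL2L1 in the libraries labelled BCLXL lay within 0.41 (SE 0.20) of those labelled BCL2, which per the labels carry BCL2 and not BCL-xL. A wrong label in only 1 group and a difference of the control cells themselves stay open and were not tested.

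The second pattern is the set of transcripts abundant only in the libraries labelled BCLXL. RNA of other tissue in these libraries is a candidate explanation: 76.9% of the intestinal list (20 of 26) and 83.3% of the fibroblast list (10 of 12) reached 1 CPM in both and stayed under 1 CPM in the other 4, against at most 13.3% for the liver, exocrine pancreas, lung, squamous, brain and kidney lists (13.3, 10, 10, 0, 0 and 10%). The shares were 83.3% for plasma cell, 58.3% for blood cell, 44.4% for smooth muscle and 12.5% for endothelial genes, and 3 intestinal and 2 fibroblast genes exceeded 1 CPM in another library. The fibroblast, blood cell and endothelial lists were fixed before the data were examined. The other lists were written after some levels had been seen, so the choice of members may partly set their shares. Whether the MCF7 cells themselves made the immunoglobulin transcripts stays open: 7 of 10 constant genes stood at 5 CPM or more in both libraries. All 7 were heavy chain genes, and 0 of the 3 light chain genes reached that level. Reads without a unique position were not counted, so the levels of near-identical heavy chain genes are uncertain. IGLC2 stood at 2.57 and 2.75 CPM, IGLC3 at 5.57 and 1.82 CPM, and IGKC had 0 counts in all 6 libraries (a gene without any count may lie outside what the counting could see, which was not tested). The condition that a light chain gene pass was added after these values were seen. Whether genes lower in these libraries were only diluted stays open, since the breast luminal transcription factors had a median log2 fold change of −0.56 against PSFFV with 7 of 9 lower and a range of −1.12 to 0.21, and expression change and dilution cannot be told apart where the clone and the other RNA coincide.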
